A study of Brassica carinata and Brassica napus and Brassica carinata x Brassica napus with 3 samples.

How the data were processed

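Floral buds of B. carinata, B. napus and an interspecific hybrid between them were compared, with 1 RNA-seq library per group, sequenced on the Illumina HiSeq 2000 per the labels. Per the labels' protocols RNA was extracted with Trizol and treated with DNase. The tissue stage of the buds, the direction of the cross and the generation of the hybrid are not given in the sources used here. The assembler, aligner and counter are not given in the sources used here either.

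The deposited table holds raw read counts per assembled sequence and RPKM values (reads per kilobase and per 1000000 reads) for each library, with sequence length and best hits in Nr, Nt and Swiss-Prot with their scores, per the file headers. The deposited counts summed exactly to the totals named in the headers, and 100% of the deposited RPKM values equalled the count divided by length and total, within 5e-05. There were 157663 sequences of 200 to 21009 bases (median 598), of which 88944 belonged to clusters and 68719 stood alone. An Nr hit was given for 123106, a Swiss-Prot hit for 81150, and 10331 had no read in any library. Parental copies of a gene can be assembled as separate sequences, and reads of near-identical copies can be split between them, so a ratio of 1 sequence can reflect sequence type and not gene output. Summed RPKM also weighs short fragments more than long ones.

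RPKM was used as deposited. The log2 ratio was taken after adding 1 RPKM, which understates the change of low sequences, and a sequence counted as apart at 2-fold with at least 5 RPKM in the higher library. The mid-parent value was the arithmetic mean of both parental RPKM values. No test across samples was possible with 1 library per group, and edgeR and DESeq2 have no residual degrees of freedom in this design. Read ratios have exact conditional binomial intervals (95%), which cover counting error only. They may be too narrow even for that, because reads without molecular identifiers are not independent molecules. Shares have Clopper-Pearson intervals, which treat the counted sequences or reads as independent. With 1 library per group, no interval covers variation between libraries. A count of 0 was set to 3 reads per library for bounds written as at least N-fold.

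Before the data were examined, 14 gene lists with 245 Arabidopsis genes were fixed, together with the comparisons, the alternatives and the rule for named genes. The lists cover sporopollenin and exine synthesis, tapetal secretion and pollen coat, anther cell fate and tapetal regulators, meiosis, late pollen and pollen tube, floral organ identity, gynoecium and ovule, photosynthesis, nectary, seed storage, glucosinolates, DNA methylation and small-RNA silencing, heat shock, and reference genes. The rule names, per pairwise comparison, up to 4 members of each list with the largest absolute log2 ratio, a fixed set of anther and floral genes (AMS, MS1, DYT1, MYB80, SPL/NZZ, DMC1, ACOS5, CYP703A2, CYP704B1, MS2/FAR2, A9, AG, AP3, PI), and the 5 highest and 5 lowest ratios among sequences with at least 20 RPKM whose annotation names a product. Sequences annotated as unknown, hypothetical, predicted, uncharacterized or the like are left out of that ranking, even where their ratio is more extreme. Where members were too many, those of the hybrid against its parents came first. Genes were matched by Arabidopsis locus identifier where an annotation gave one, and otherwise by symbol or synonym as whole words, and RPKM was summed per gene. In total 171 of 245 genes were matched. DYT1, MYB80 and CYP704B1 were not matched by name, which does not show that they were absent. For length, not all genes that the rule names are printed, and 1 of them is not reported here.

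Parts of the matching were settled after the list members and their reads had been seen. A Swiss-Prot name was used only where its score was at least 0.6 of the Nr score. The first value tried was 0.8, which dropped Brassica matches such as those of MET1. Symbols in the Nr name were always used, and for 23 genes matches were removed where the annotation named another protein (for example beta-amylase for BAM1, and a profilin numbered differently for PRF5). The criterion was the annotation text, but some removed matches were flat or high in B. carinata, so that their removal deepened the late pollen difference. All list medians were therefore recomputed with 0.8, with no ratio, without removals and with symbol words only where nothing else matched.

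A list's median has a 95% order-statistic interval where at least 6 members were measured. It also has a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. These percentiles were computed for the main matching and settings only. Scaling factors came from edgeR 4.0.16 in R 4.3.3, and all else from Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The counting rule was tested on simulated data drawn at the real means and totals, with counting error alone and no variation between libraries. Changes were placed only on sequences with a pooled level of at least 2 times the floor of 5 RPKM. Recovery nearer the floor and false calls between replicate libraries were therefore not measured. For the hybrid against B. carinata, 50 of 50 sequences changed 3-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold were called in the right direction among 34568 tested, as were 16 of 50 changed exactly 2-fold. With no sequence changed, 5 of 34607 were called. Simulated hybrids at the higher and at the lower parent were added after seeing the data. Alternatives tried were TMM factors and the median of ratios, pseudocounts of 0.1 and 5, floors of 1 and 20 RPKM or none, a 4-fold threshold, sums by best hit, sequences found in all 3 libraries, and a geometric mid-parent. For sequences found in 1 parent alone they were the same floors and absence below 0.1 RPKM. For lists they were both scalings, both pseudocounts, the sequence with the highest mean per gene, and sums over sequences found in all 3 libraries. Sums of RPM (reads per 1000000 reads) in place of RPKM were added after seeing the data.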

Results

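RNA from floral buds of Brassica carinata, of Brassica napus and of an interspecific hybrid between them was sequenced, with 1 library for each of the 3 groups. Reads were counted on 157663 assembled sequences, without a genome position. The B. carinata library held 28.1 M counted reads (M, 1000000 reads), the hybrid library 27.1 M and the B. napus library 28.2 M. At least 1 read fell on 125700 sequences in B. carinata, on 134002 in the hybrid and on 107023 in B. napus. At these depths a count of 0 allows up to 0.107 RPM (reads per M reads) in B. carinata, 0.111 in the hybrid and 0.106 in B. napus. Each difference below compares libraries and has no replicate check. Intervals (95%) of read ratios cover counting error only. Those of shares treat the counted sequences or reads as independent, and those of medians cover the spread among a list's genes or a set's sequences. Values are RPKM, summed over the sequences of a gene where a gene is named, and log2 ratios were taken after adding 1 RPKM. Other scalings shift all RPKM ratios of a comparison by the same amount, and log2 ratios of low genes by less because of the added 1 RPKM. Before that addition TMM factors move B. carinata over B. napus by 0.28, hybrid over B. carinata by 0.18 and hybrid over B. napus by 0.46, and the median of ratios moves them by 0.28, -0.31 and -0.03.

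The parental comparison asked how the floral buds of the 2 species differed before the hybrid was considered. Genes that make sporopollenin and the pollen exine, the outer pollen wall, stood higher in B. carinata. Of 11 measured members, 9 were at least 2-fold higher in B. carinata and none was 2-fold lower. DEX1 went the other way by reads, at a ratio of 0.366 (interval 0.322 to 0.416). With sums of RPM 10 genes were higher and 1 lower, and with the sequence of highest mean per gene 8 and 1. The list's median log2 ratio was 2.297 (interval 0.90 to 3.02), above all 10000 random lists of matched expression. ACOS5, an acyl-CoA synthetase of the sporopollenin pathway, had 262 RPKM in B. carinata and 14.5 RPKM in B. napus, a read ratio of 26.9 (interval 23.9 to 30.3). CYP703A2, a fatty acid hydroxylase of the same pathway, had 88.7 and 12.6 RPKM, and TKPR2, a reductase, had 56.1 and 8.83 RPKM. ABCG26, a transporter of the tapetum, had 240.3 and 28.7 RPKM, but a smaller read ratio of 3.48 (interval 3.32 to 3.65). MS2/FAR2, a fatty acyl reductase, had 154.6 and 36.5 RPKM. The mixed list of regulators of anther cell fate and of the tapetum, the anther layer that feeds the pollen, had 7 of 11 genes at least 2-fold higher in B. carinata and none 2-fold lower (median 1.099, interval 0.06 to 2.88, percentile 98.7). The count was 4 of 11 with a pseudocount of 5, and 4 of 11 with a median of 0.30 over sequences found in all 3 libraries. With the sequence of highest mean per gene, 5 of 10 were higher and 3 lower. BHLH091 had 85.6 against 2.45 RPKM, MS1 13.4 against 0.96 RPKM, AMS 68.3 against 21.8 RPKM and SPL/NZZ 24.8 against 11.0 RPKM.

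Genes of mature pollen and the pollen tube went the other way. Of 14 measured members, 9 were at least 2-fold lower in B. carinata and 1 was higher, with a median log2 ratio of -1.77 (interval -4.83 to 0.26) at the 0.01 percentile of random lists. The pectin methylesterase PPME1 had 0.28 RPKM in B. carinata and 127 RPKM in B. napus, and VGD1, a second pectin methylesterase, 1.32 and 127 RPKM. The proton pump AHA6 had 0.99 and 55.5 RPKM, and the actin-binding proteins PRF4 and ADF7 had 0.53 and 30.0 RPKM and 0.24 and 21.99 RPKM. MYB101 was the exception, with 64.2 RPKM in B. carinata and 26.6 RPKM in B. napus. That percentile holds for the matching settled after the reads had been seen. Keeping the name matches that had been removed as other proteins left 16 measured genes and a median of -0.87, without a percentile. Of these, 8 were lower and 2 higher. HAP2/GCS1 counted as lower in B. carinata, at 5.14 and 11.96 RPKM. Sequences annotated as HAPLESS 2-A were not counted under HAP2/GCS1 and went the other way, at 1711 and 652 RPKM. The list of tapetal secretion and pollen coat was mixed, with 3 of 4 measured genes at least 2-fold lower in B. carinata and 1 higher (median -1.37). The pollen coat genes GRP17, EXL4 and EXL6 had 3.63 and 141.5 RPKM, 155.4 and 383 RPKM, and 97.9 and 268 RPKM. The tapetal marker A9 had 3665 RPKM in B. carinata and 729 RPKM in B. napus. With the sequence of highest mean per gene, 1 of the 4 was lower and 1 higher.

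Of 10 floral organ identity genes 9 lay within 2-fold between the parents (median 0.49, interval -0.99 to 0.84). With TMM factors, the median of ratios or the sequence of highest mean per gene, 3 were higher in B. carinata and 1 lower. AP3 had 350.02 RPKM in B. carinata and 195.7 RPKM in B. napus, PI 291.3 and 191.1 RPKM and AG 129.5 and 95.7 RPKM, while SHP2 had 3.12 and 27.8 RPKM. Meiosis genes had a median of 0.57 (interval -0.06 to 1.01), with MRE11 at 16.1 and 2.90 RPKM and MSH4 at 14.9 and 50.5 RPKM. Genes of DNA methylation and small-RNA silencing had a median of 0.71 (interval -0.01 to 1.06), and 7 of 19 were at least 2-fold higher in B. carinata, led by CMT3 with 19.1 and 1.66 RPKM. The count was 4 of 19 with a pseudocount of 5, 4 over sequences found in all 3 libraries (median 0.38) and 3 with sums of RPM (median 0.29). Photosynthesis genes, from green sepal and leaf cells, had a median of 0.08 (interval -0.69 to 0.81), gynoecium and ovule genes -0.17 (interval -1.87 to 0.81), glucosinolate genes 0.23 (interval -1.62 to 1.43) and commonly used reference genes 0.22 (interval -0.63 to 1.47). Of the heat shock list only HSP70-4 and HSP90.1 were measured. HSP70-4 had 160.8 and 2.02 RPKM, and HSP90.1 had 427 reads in B. carinata and 0 in B. napus. The nectary invertase CWINV4 had 6.42 and 60.0 RPKM. No seed storage gene reached 5 RPKM, with 2 of 9 matched.

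In all, 36899 of 49318 sequences with at least 5 RPKM in the higher library were at least 2-fold apart, 20611 higher in B. carinata (55.9%) and 16288 higher in B. napus. Over sequences found in all 3 libraries the direction turned, with 11884 higher in B. carinata (47.1%) and 13367 lower. Parental copies of a gene can be assembled apart, and summing sequences with the same best hit left 12858 of 25863 units apart. The highest ratios belonged to sequences annotated as a lipid-associated family protein (120037 reads against 0, at least 40149-fold higher), a heat stress-induced protein (72245 against 0, at least 24164-fold) and the receptor-like kinase PERK2 (90902 against 0, at least 30404-fold). A lipid-transfer protein 6 sequence (33293 reads against 1) and one annotated as HAPLESS 2-A (35484 against 0, at least 11868-fold higher) came next. The lowest were plastid 30S ribosomal protein S3 (122 reads against 186534), a peptidyl-prolyl isomerase (7 against 14517) and plastid NAD(P)H-quinone oxidoreductase subunit 1 (3 against 28962). A pollen coat protein class A (0 against 10118, at least 3361-fold lower) and a lipid-transfer protein A sequence (43 against 38407) completed them. Ratios of single sequences can reflect sequence type, and several shrank when all sequences with the same best hit were summed. The sums in B. carinata and B. napus were 5257 and 131 RPKM for the lipid-associated protein, 1923 and 37.2 RPKM for PERK2, and 1711 and 652 RPKM for HAPLESS 2-A. They were 4128 and 3951 RPKM for lipid-transfer protein 6, 2310 and 3207 RPKM for the isomerase and 319 and 2106 RPKM for lipid-transfer protein A.

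The hybrid was then compared with B. carinata. Exine genes stood lower in the hybrid, as 10 of 11 were at least 2-fold lower and none was higher. The count was 8 with TMM factors or a pseudocount of 5 and 7 with the sequence of highest mean per gene, and DEX1 was higher by reads, at a ratio of 1.52 (interval 1.32 to 1.76). The median log2 ratio was -1.39 (interval -2.17 to -1.01), below all 10000 random lists. QRT3, which separates pollen grains from the tetrad, had 20.6 RPKM in the hybrid and 107.2 RPKM in B. carinata, a read ratio of 0.18 (interval 0.168 to 0.193). ACOS5 had 57.4 RPKM in the hybrid, CYP703A2 43.5, ABCG26 82.9, TKPR1/DRL1 22.2 against 66.9, SWEET8/RPG1 18.49 against 84.3 and MS2/FAR2 60.2 RPKM. In the tapetal secretion and pollen coat list, A9 had 853 RPKM, at a read ratio of 0.233 (interval 0.229 to 0.237) to B. carinata, and EXL4 was also lower, but GRP17 was higher (median -0.76, and 0.27 with TMM factors). Among the anther regulators, 4 of 11 were at least 2-fold lower and none was higher. These were BHLH091 at 12.3 RPKM, MS1 at 2.16 RPKM, SPL/NZZ at 6.19 RPKM and AMS at 28.6 RPKM. The list's median was -0.18 (interval -2.19 to 0.15), since EMS1/EXS, TPD1, SERK1, RPK2 and BAM1, receptors and ligands of early anther layers, lay within 2-fold.

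Of the 14 measured late pollen genes, 10 lay within 2-fold between the hybrid and B. carinata. Their median log2 ratio was -0.25 (interval -0.52 to 0.23), and -0.47 with a pseudocount of 0.1. VGD1, PPME1, AHA6, PRF4 and ADF7 were so low in both that the added 1 RPKM hides their ratios, and AHA6 had a read ratio of 0.438 (interval 0.286 to 0.658). MYB101 (8.33 RPKM in the hybrid) and the potassium channel AKT6/SPIK (0.96 against 6.89 RPKM) were lower in the hybrid, while BUPS1 (11.2 against 3.52 RPKM) and GEX1 (6.64 against 2.501 RPKM) were higher. Glucosinolate genes had a median of -1.05 (interval -1.51 to 0.18), with 6 of 11 at least 2-fold lower in the hybrid. The median was 0.12 with the sequence of highest mean per gene (2 higher and 3 lower), and -0.51 with a pseudocount of 5 (2 lower). CYP83A1 had 2.51 against 12.2 RPKM, UGT74B1 7.13 against 22.2 RPKM, MYB28 10.6 against 25.1 RPKM and SOT16 7.93 against 18.9 RPKM.

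Meiosis genes showed no common shift between the hybrid and B. carinata, with 16 of 20 within 2-fold and a median of -0.01 (interval -0.54 to 0.44). DMC1, the meiotic recombinase, had 31.9 RPKM in the hybrid and 22.8 RPKM in B. carinata. Those at least 2-fold higher in the hybrid included SYN1/REC8 (8.85 against 2.84 RPKM) and MSH4 (38.4 RPKM), and MMD1/DUET (3.02 against 8.12 RPKM) was at least 2-fold lower. Of the floral identity genes SHP2 (22.2 RPKM) and SUP (6.48 against 1.83 RPKM) were higher in the hybrid. AP3 had 251.5 RPKM, PI 312.01 RPKM and AG 103 RPKM in the hybrid. The list's median was 0.26 (interval -0.33 to 1.41). Silencing genes lay within 2-fold in 19 of 19 cases (median -0.05, interval -0.17 to 0.32). Gynoecium genes had a median of 0.28 (interval -0.03 to 0.84), photosynthesis genes -0.21 (interval -0.99 to 0.18, with LHCB3 at 6.94 against 20.7 RPKM) and reference genes -0.01 (interval -1.21 to 0.45). HSP70-4 had 23.0 RPKM in the hybrid and HSP90.1 4.05 against 13.4 RPKM.

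Between the hybrid and B. carinata, 15678 of 42845 sequences were at least 2-fold apart, 8141 higher in the hybrid and 7537 lower. The share higher in the hybrid was 51.9%, but 64.3% with TMM factors and 32.1% with the median of ratios. The highest ratios belonged to single sequences of a peptidyl-prolyl isomerase (4727 reads against 7), metallothionein-like protein type 2 (42951 against 170), histone H3.2 (4782 against 11), HAPLESS 2-A (5696 against 7) and the stress-induced protein KIN2 (13062 against 64). The lowest among named products were sequences of histone H3.2 (2 reads against 1088), nucleoside diphosphate kinase 1 (0 against 664, at least 213-fold lower), lipid-transfer protein 12 (13 against 2747), purple acid phosphatase 6 (16 against 1272) and 40S ribosomal protein S14 (2 against 511). A sequence of 9840 bases, outside this ranking, was more extreme, at 744 reads against 360757, which is 1.28% of the B. carinata reads. It had 0 reads in B. napus, and its origin was not tested. Summed by best hit, HAPLESS 2-A was lower in the hybrid, at 586 RPKM against 1711 RPKM in B. carinata. The isomerase then had 2616 and 2310 RPKM, metallothionein type 2 had 6863 and 1823, histone H3.2 had 3826 and 2992, and KIN2 had 2130 and 1643. Nucleoside diphosphate kinase 1 had 985 and 1049 RPKM, lipid-transfer protein 12 had 3211 and 12445, purple acid phosphatase 6 had 14.2 and 532, and S14 had 33.0 and 55.7.

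Against B. napus, the hybrid had far lower levels of late pollen genes. Of 14 measured members 9 were at least 2-fold lower in the hybrid and none was 2-fold higher. The median log2 ratio was -1.96 (interval -5.35 to 0.06), below all 10000 random lists. With the removed name matches kept, the median was -1.65 over 16 genes, and no percentile was computed for it. PPME1 had 0.50 RPKM in the hybrid, a read ratio to B. napus of 0.0030 (interval 0.0014 to 0.0056), and VGD1 had 0.65 RPKM. AHA6 had 0.38 RPKM, and AGP11 and AGP6, arabinogalactan proteins of pollen, had 8.14 against 115.2 RPKM and 11.3 against 55.4 RPKM. PRF4 had 2 reads in the hybrid and ADF7 1 read, at read ratios to B. napus of 0.0070 (interval 0.0008 to 0.0257) and 0.0026 (interval 0.0001 to 0.0146). Among pollen coat genes, EXL4 had 50.2 RPKM, GRP17 18.6 RPKM and EXL6 103.9 RPKM in the hybrid, each at least 2-fold below B. napus. With TMM factors 2 of 5 genes of the tapetal secretion and pollen coat list were lower and 1 higher, and 2 of 4 were lower with the sequence of highest mean per gene. CWINV4 had 3.67 RPKM, and the glucosinolate genes MAM1 and CYP83A1 had 0.29 against 7.92 RPKM and 2.51 against 15.5 RPKM.

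Exine genes in the hybrid were at least 2-fold higher than in B. napus for 4 of 11 and within 2-fold for 7 (median 0.71, interval -0.22 to 1.71, percentile 99.2). The 4 were ACOS5, CYP703A2, ABCG26 and TKPR2, at read ratios of 5.19 (interval 4.58 to 5.90), 5.01 (interval 4.53 to 5.55), 1.66 (interval 1.57 to 1.75) and 3.41 (interval 2.95 to 3.95). With sums of RPM 3 of 11 were higher, and 6 of 11 with TMM factors or the sequence of highest mean per gene. Under TMM factors the median was 1.16 over B. napus and -1.21 over B. carinata. BHLH091 was also higher in the hybrid, at 5.04 times the reads (interval 3.62 to 7.18). A9 had a read ratio of 1.17 (interval 1.14 to 1.20) and AMS of 1.04 (interval 0.976 to 1.11). Anther regulators had a median of 0.50 (interval -0.03 to 1.49).

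Silencing genes stood higher in the hybrid than in B. napus by summed RPKM, with a median of 0.65 (interval 0.36 to 0.92, percentile 99.6). DCL1, the gene at that median, had 16.4 against 10.1 RPKM but a read ratio of 1.01 (interval 0.91 to 1.12). Not every read ratio was smaller than the RPKM ratio, as RDR6 had 7.10 against 3.51 RPKM and a read ratio of 2.93. The DNA methyltransferases CMT3 (16.05 against 1.66 RPKM) and DRM2 (34.8 against 10.2 RPKM) passed 2-fold, whereas 11 of 19 genes did with TMM factors and 9 of 18 with the sequence of highest mean per gene. Meiosis genes had a median of 0.47 (interval 0.06 to 0.86), with 4 of 20 at least 2-fold higher by summed RPKM. Their read ratios were below 2, at 1.82 for MRE11, 1.36 for PRD1, 1.26 for MUS81 and 1.98 for TAM/CYCA1-2. No meiosis gene passed 2-fold with sums of RPM, with a pseudocount of 5 or over sequences found in all 3 libraries, and 8 of 20 did with TMM factors. Under TMM factors the silencing and meiosis medians became 1.102 and 0.88. Floral identity genes had a median of 0.39 (interval 0.11 to 0.88), gynoecium genes -0.03 (interval -1.63 to 1.09), photosynthesis genes -0.18 (interval -0.89 to 0.52), glucosinolate genes -0.21 (interval -2.23 to 0.15), and reference genes 0.13 (interval -0.40 to 0.52). With TMM factors the sign turned in the glucosinolate list (0.22) and the gynoecium list (0.39), and the photosynthesis median also became positive.

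Between the hybrid and B. napus, 17949 of 41134 sequences were at least 2-fold apart, 11551 higher in the hybrid and 6398 lower. The share higher in the hybrid was 64.4%, and 84.5% with TMM factors. The highest ratios were for sequences of lipid-transfer protein 6 (20585 reads against 1), a peptidyl-prolyl isomerase (19921 against 0, at least 6922-fold higher) and a heat stress-induced protein (22833 against 0, at least 7934-fold). Metallothionein MT2-4/MT2-25 (11506 against 0, at least 3998-fold) and PERK2 (29224 against 0, at least 10154-fold) followed. The lowest were the plastid sequences of 30S ribosomal protein S3 (147 against 186534), NAD(P)H-quinone oxidoreductase subunit 1 (12 against 28962) and ycf1 (0 against 17430, at least 5574-fold lower), a pollen coat protein class A (2 against 10118) and a maternally expressed family protein (0 against 5906, at least 1889-fold lower). Summed by best hit, the isomerase was lower in the hybrid, at 2616 RPKM against 3207 RPKM in B. napus. Lipid-transfer protein 6 then had 5424 and 3951 RPKM, MT2-4/MT2-25 had 1916 and 1470, PERK2 had 672 and 37.2, and ycf1 had 344 and 564.

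**Figure D1:**
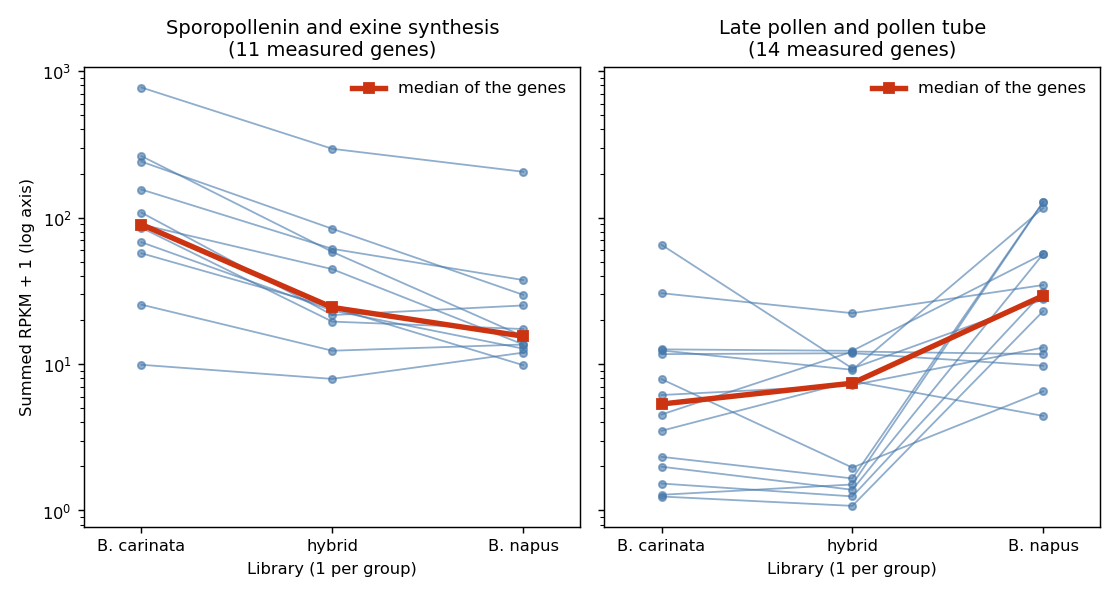
Summed RPKM plus 1, on a log axis, of each measured gene of the exine list (11 genes) and the late pollen list (14 genes) in the 3 libraries, 1 line per gene, with the median of the genes as squares. Of the 11 exine genes 10 were highest in B. carinata (ACOS5 at 262 RPKM), and PPME1 and VGD1 reached 127 RPKM in B. napus alone.

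The hybrid was next set against the mean of its parents. Late pollen genes lay below that mean, with 9 of 14 at least 2-fold lower and a median log2 ratio of -2.09 (interval -4.40 to 0.15), and exine genes had a median of -0.69 (interval -1.40 to -0.46). Both were below all 10000 random lists. With the removed name matches kept, the late pollen median was -1.68, and no percentile was computed for it. Glucosinolate genes had a median of -0.69 (interval -2.08 to -0.17) and photosynthesis genes -0.34 (interval -0.64 to -0.12), and the latter became 0.035 with TMM factors. Floral identity genes had a median of 0.42 (interval -0.12 to 0.58), silencing genes 0.27 (interval 0.17 to 0.46), meiosis genes 0.14 (interval -0.02 to 0.44), anther regulators 0.12 (interval -1.40 to 0.34), gynoecium genes 0.05 (interval -0.98 to 0.63) and reference genes -0.06 (interval -0.66 to 0.30).

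Of 37690 sequences, 4205 were at least 2-fold from the parents' mean, 1743 higher and 2462 lower. The share higher was 41.5%, 70.4% with TMM factors and 24.6% with the median of ratios. A hybrid drawn at the parents' arithmetic mean with counting error alone gave 0 apart from that mean. Against the geometric mean, which lies below the arithmetic one wherever parents differ, 11563 sequences were apart, 88.9% of them higher. The same simulated hybrid had 7855 apart from the geometric mean, all of them higher. In classes by 2-fold rules, 395 of 50663 sequences lay above both parents (0.78%) and 311 below both (0.61%). With TMM factors there were 955 and 204. A hybrid simulated at the level of the higher parent lay above both for 1 of 51856 sequences, and one at the lower parent lay below both for 8 of 49615, from counting error alone. With the parents apart, the hybrid was like B. carinata for 14963 sequences (29.5% of all classed) and like B. napus for 9701 (19.1% of all classed). The simulated hybrid at the parents' mean was like B. carinata for 30.6% and like B. napus for 22.4% of all classed. A further 12508 sequences were between the parents or within 2-fold of both, 11703 were within 2-fold throughout and 1082 met none of these rules. The 2 comparisons behind each class share the hybrid library.

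**Figure D2:**
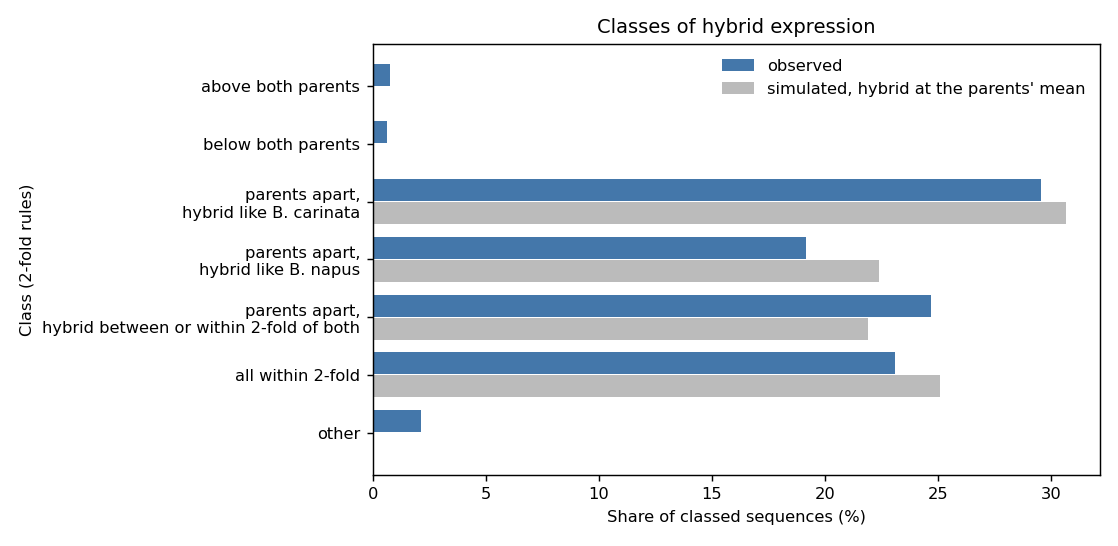
Share of classed sequences (%) in each class of hybrid expression, observed (dark bars, 50663 sequences) and in a simulation with the hybrid at the mean of its parents (light bars, 49601 sequences). Sequences above and below both parents made up 0.78% and 0.61% of those observed. In the simulation these classes are empty by construction, since the mean lies between the parents.

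Last, sequences found in 1 parent alone were followed into the hybrid. Of 8698 sequences with at least 5 RPKM in B. carinata and no reads in B. napus, 98.6% (Clopper-Pearson interval 98.3 to 98.8) had reads in the hybrid, at a median of 0.501 times the B. carinata level (interval 0.494 to 0.508). Of 2846 sequences found in B. napus but not in B. carinata, 92.9% (interval 91.9 to 93.8) had reads in the hybrid, at a median of 0.452 times the B. napus level. These levels use RPKM as deposited and were not recomputed with other scalings. For the same sequences, TMM factors would shift their log2 by 0.18 (B. carinata set) and 0.46 (B. napus set). The median of ratios would shift them by -0.31 and -0.03. Either would put the B. napus median above the B. carinata median. The hybrid drawn at the parents' mean had reads on 100% of both sets. Without reads in the hybrid were 203 sequences of B. napus alone.

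**Figure D3:**
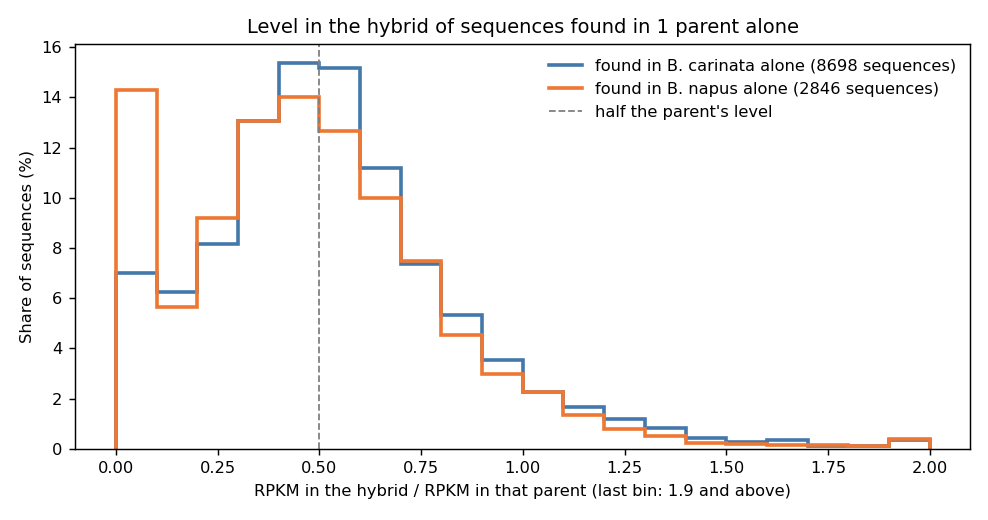
Histogram of the level in the hybrid relative to the parent, in RPKM, for sequences found in B. carinata alone (8698) and in B. napus alone (2846), as a share of each set (%), with a dashed line at 0.5. The medians were 0.501 and 0.452 with RPKM as deposited, and other scalings would move them. The lowest bin holds 7.002% of the first set and 14.3% of the second, where it is the tallest bin.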

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

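No paired analysis was possible because each group has 1 library and no result comes from a test across samples. Sums of RPM and the changes in name matching were chosen after seeing the data, and all other alternatives before. The median log2 ratio of exine genes kept its sign in all 11 alternatives for B. carinata over B. napus, hybrid over B. carinata and hybrid over the mid-parent, and that of late pollen genes did so for B. carinata over B. napus, hybrid over B. napus and hybrid over the mid-parent. Late pollen medians for B. carinata over B. napus ranged from -3.95 with the sequence of highest mean per gene to -0.87 without removal of matches. No change in name matching moved a list median outside its main interval (for lists with under 6 measured genes, the range of its genes). These intervals can be wide, so staying inside does not mean a small change. The late pollen median moved from -1.77 to -0.87 inside an interval of -4.83 to 0.26. Across lists, 554 medians stayed inside the main interval, 17 moved outside it and 1, whose main interval excluded 0, reversed. Changes of sign were more frequent, in 34 of 572 medians, mostly where the main interval held 0. With the sequence of highest mean per gene they included glucosinolates over B. carinata in the hybrid (0.12), glucosinolates for B. carinata over B. napus (-1.14) and floral identity genes for B. carinata over B. napus (-0.26). Of the counts of sequences apart, 17 stayed within 1.5 times the main count and 28 did not, and of the class sizes 29 did and 48 did not. Floors, sums and the limit to sequences found in all 3 libraries changed the number of units tested by construction. The 4-fold threshold left that number alone and is stricter, and for the other changes the cause was not tested. With a floor of 1 RPKM or none, counts of sequences apart moved to 80406 (parents), 35901 (hybrid against B. carinata), 45166 (hybrid against B. napus), 11466 (hybrid against mid-parent), and class sizes moved to 1181 (above both), 555 (below both), 30967 (like B. carinata), 22525 (like B. napus), 26550 (between), 31203 (all within 2-fold), 4963 (other). With a floor of 20 RPKM, counts of sequences apart moved to 10099 (parents), 4106 (hybrid against B. carinata), 4753 (hybrid against B. napus), 1226 (hybrid against mid-parent), and class sizes moved to 107 (above both), 124 (below both), 3908 (like B. carinata), 2621 (like B. napus), 3583 (between), 3112 (all within 2-fold), 295 (other). With a pseudocount of 5, counts of sequences apart moved to 8505 (hybrid against B. carinata), 1846 (hybrid against mid-parent), and class sizes moved to 133 (above both), 97 (below both), 9765 (like B. carinata), 6270 (like B. napus), 19302 (all within 2-fold). With a pseudocount of 0.1, class sizes moved to 564 (below both). At 4-fold, counts of sequences apart moved to 6329 (hybrid against B. carinata), 10255 (hybrid against B. napus), 1062 (hybrid against mid-parent), and class sizes moved to 66 (above both), 42 (below both), 22202 (all within 2-fold), 539 (other). Summed by best hit, counts of sequences apart moved to 12858 (parents), 5404 (hybrid against B. carinata), 6654 (hybrid against B. napus), 2543 (hybrid against mid-parent), and class sizes moved to 256 (above both), 5346 (like B. carinata), 3221 (like B. napus), 4390 (between). Over sequences found in all 3 libraries, counts of sequences apart moved to 11951 (hybrid against B. napus), 2523 (hybrid against mid-parent), and class sizes moved to 259 (above both), 9227 (like B. carinata). With RPM summed by best hit, counts of sequences apart moved to 8508 (parents), 3249 (hybrid against B. carinata), 4132 (hybrid against B. napus), 1486 (hybrid against mid-parent), and class sizes moved to 100 (above both), 173 (below both), 3352 (like B. carinata), 2103 (like B. napus), 3058 (between), 489 (other). With a geometric mid-parent, counts of sequences apart moved to 11563 (hybrid against mid-parent). With TMM factors, class sizes moved to 955 (above both), 204 (below both), 7631 (between), 2174 (other). With the median of ratios, class sizes moved to 244 (above both). Without a floor the class of all within 2-fold held 60591. For sequences of B. carinata alone, the share with reads in the hybrid was 92.1% and the median level 0.445 with a floor of 1 RPKM, and 99.4% and 0.558 with a floor of 20. For those of B. napus alone, the share was 86.7% and the median 0.380 with a floor of 1 RPKM, the share was 90.8% with a floor of 20, and 94.2% with absence taken as below 0.1 RPKM. Photosynthesis genes in the hybrid over the mid-parent reversed from -0.34 to 0.035 with TMM factors. With TMM factors, medians of the hybrid over the mid-parent moved to 0.37 for anther regulators, 0.44 for meiosis, 0.66 for floral identity and 0.52 for silencing genes. Those of the hybrid over B. napus moved to 0.88 for meiosis, 0.22 for glucosinolates, 1.102 for silencing genes and 0.55 for reference genes. With the median of ratios, meiosis moved to -0.034 and silencing genes to 0.076 in the hybrid over the mid-parent, and silencing genes to -0.34 over B. carinata. The 2 heat shock genes, of which HSP90.1 had no read in B. napus, moved to 6.66 and 3.22 for B. carinata over B. napus with pseudocounts of 0.1 and 5. For the hybrid over B. napus these 2 genes moved to 4.41 and 1.43 with the same pseudocounts, 2.24 with the sequence of highest mean and 1.98 with sequences found in all 3 libraries. Depth limits the low late pollen genes in the hybrid, where ADF7 had 1 read.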

Other observations

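All tests of explanations in this part were chosen after the patterns had been seen. Those on sequences of B. napus alone were written before their own results were known, and the rules of the others after theirs.

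A further set of genes lay far below both parents in the hybrid. With a rule chosen after seeing the data (at least 4-fold from both parents, at least 20 RPKM in the highest library, sums by best hit), 24 units lay below both parents and 17 above. Units named here are examples from the first group, without a test of any shared theme. Of the 17 above both parents, 8 held nuclear ribosomal sequences and 6 others had no product name. Purple acid phosphatase 5 had 2.18 RPKM in the hybrid, 83.7 in B. carinata and 77.95 in B. napus. Purple acid phosphatase 6 had 14.2, 532 and 184 RPKM, purple acid phosphatase 11 had 6.49, 154.4 and 48.1, and purple acid phosphatase 25 had 1.65, 28.6 and 30.05. Sugar transport protein 2, known from early microspores, had 3.42, 42.1 and 27.6 RPKM, and LOB domain-containing protein 27, a regulator of microspore division, had 1.01, 9.21 and 26.8. Polyadenylate-binding protein 5 had 32.4, 147.3 and 394.7 RPKM, CYP86C4 33.2, 149.8 and 281.5, and a hydroxyproline-rich glycoprotein 18.52, 199.9 and 173.7.

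Summed over the list, late pollen genes were low in the hybrid and in B. carinata, at 62.0 and 94.01 RPM against 584.8 in B. napus. This did not hold for every member. Scaling between libraries moves all genes alike, and under both other scalings at least 8 of 14 genes kept a counting interval of hybrid over B. napus wholly below 0.5, which argues against it. Reads split between parental copies would leave the B. napus-type sequences of these genes in the hybrid near the level of other such sequences, but their median was 0.00677 of the B. napus level (10 sequences) against 0.477 for 6713 others, which argues against a split for that pair. For B. carinata against B. napus a split stays open. The list together with its protein families reached 0.74 of the B. napus reads, but the list is too small a part of that sum to decide. Arabinogalactan proteins alone gave 3155 RPM in B. carinata and 3983 in B. napus, against 94.01 and 584.8 for the list. Bud stage or cell makeup may contribute, as exine genes went the other way in B. carinata over B. napus (median log2 ratio 2.297). In the hybrid over B. napus their median was 0.71, with an interval that held 0 (-0.22 to 1.71). With 1 library per group, bud stage or cell makeup cannot be told apart from genotype.

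Ribosomal and plastid sequences in the hybrid were mostly of the B. carinata type, defined as at least 20-fold higher in that parent. Of the hybrid's 305543 reads on typed nuclear ribosomal sequences, 93.97% (interval 93.9 to 94.1) lay on the B. carinata type, against 61.2% expected from the parents' mean, which argues against equal use of both types. The share rests on 9 B. carinata-type and 2 B. napus-type sequences, and the largest of the 9 held 84.1% of the hybrid's reads on that type. Without it the share was 71.3%, against 22.04% expected. Reads shared between near-identical sequences are argued against as the whole cause of the 93.97%, if reads were placed alike in all libraries. At the largest rate that the definition of the types allows, sharing would give 64.001%. The B. napus-type plastid and mitochondrial sequences had medians of 0.00394 and 0.00429 of their B. napus level in the hybrid, consistent with plastids and mitochondria from B. carinata as a hypothesis, although 3 of 33 plastid sequences stayed at 0.5 or more. Mitochondrial sequences of the B. carinata type did not rise in sum, at 249 RPM in B. carinata and 74.1 RPM in the hybrid. Their median was 0.588 of the B. carinata level, with 6 of 9 at 0.5 or more and 2 of 9 under 0.1. No biological explanation of the ribosomal share was tested, and the uptake of these RNAs by the library preparation may differ between libraries.

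Of the 2846 sequences found in B. napus alone, 203 had no read in the hybrid. Counting error around the parents' mean did not account for them, as drawing the hybrid at that mean left 0 without reads. The floor of 5 RPKM made this outcome likely beforehand. The draw cannot tell absence from a level far below the mean that was missed at this depth. Sequence from another organism is argued against as the whole source, since 122 of 134 with an Nr hit matched the Brassicaceae. The share outside was 8.96% (interval 4.71 to 15.1), against 4.90% (interval 3.90 to 6.07) for sequences with hybrid reads. These intervals overlapped, which does not rule out an excess. Those of the 203 without an Nr hit were left out of the share. Products named for pollen or pectin breakdown made up 7.88% (interval 4.57 to 12.5) against 0.757% (interval 0.463 to 1.17), so pollen transcripts are a candidate source for a part of them, and the other 92.1% name no such product.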
